A study of Homo sapiens with 24 samples.

How the data were processed

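Gene expression was measured in MCF7 cells with Phalanx human one-colour arrays. Per the labels, polyadenylated RNA was turned into cDNA, amplified by in vitro transcription with a modified nucleotide and coupled to the dye Cy5. The labels refer to a publication for growth, treatment and extraction, which is not used here. The deposited table holds values on the log2 scale for 30968 probes on 24 arrays, as the authors made them. The scale was settled from the values, since 99.7% of those under 7 were multiples of 0.5 after conversion to the linear scale, within a rounding tolerance of 5.0e-04 on the log2 scale. The background correction and the normalization behind the table are not given in the sources used here. The lowest value was 5.81 and the highest 16, which was taken as saturation and held 709 values, 14 probes being at 16 on all 24 arrays. Array medians lay between 7.011 and 7.031. As they differed by less than 0.1, the limit set for renormalizing, the deposited values were used unchanged and no probe was left out for dimness. The number of arrays and clones limits the precision.

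Groups were taken from the sample titles. The submitters describe 1 parental culture, 3 vector clones and 4 KLIP1 clones, each with 3 technical replicates. The arrays of a clone were averaged, so that n counts clones, and the parental arm has n = 1 and is assumed to vary like the other groups. Nothing in the sources used here says at which step the technical replicates were split or whether the clones of both transfections were raised side by side. The p-values between arrays of a clone therefore measure technical spread alone.

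Genes were named from the platform annotation supplied with the values. A single symbol was given for 17397 probes, several for 0, and 13571 probes were unnamed here. Of the named probes, 14670 carried a symbol current in the RefSeq gene table, 2645 were updated through a synonym and 82 kept the platform's symbol, giving 15207 distinct genes. KLIP1 was found under its platform symbol MLF1IP and renamed CENPU. No genome build accompanied the table and no coordinates are given.

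Groups were compared with limma 3.58.1 in R 4.3.3 on the 8 clone means with 1 mean per group. Moderated tests had a prior variance trend, 5 residual degrees of freedom and 5.38 prior degrees of freedom, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. An exact permutation test of 3 against 4 clones, its two-sided p taken as both tails, cannot give a p under 0.0571, so single genes were not tested that way. SE denotes the standard error from the limma fit, and intervals are 95% intervals from the same fit. The 24 gene lists, holding 792 genes of which 619 were measured, were written from textbook knowledge. They were tested with camera at a preset correlation of 0.01 with the brightest probe per gene, adjusted over the lists, with camera at an estimated correlation and with fry, directional and mixed. Differences between clones of a group were tested with a limma F test over arrays, against the spread of the technical replicates, and the share of list genes past it with a two-sided Fisher's exact test against all other named genes, adjusted over the 24 lists in both groups.

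Named genes followed a rule. CENPU and MYC came first, then up to 12 genes per direction past the threshold with every KLIP1 clone on one side of every vector clone and the higher group at or above the median of all probe means. A direction with fewer than 5 such genes was filled to 5 by the smallest unadjusted p among probes meeting the other criteria. Up to 4 members per list with the smallest p were eligible, and 5 per direction in the comparisons with the parental culture. Genes named for clone differences were the widest ranges past the F test or list members past it, and were chosen after their values were seen, as were HSPB8, the second probes and the single arrays mentioned. The groups, lists, tests of groups and lists, thresholds and naming rule, and every alternative except those stated as added, were fixed before the data were examined. Tests on heat shock genes and on splits of clones or arrays were not among these, and their timing is given where they are reported.

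Alternatives were quantile normalization, median centring, filters on the dimmest 25% and 50% of probes, eBayes without a trend or robust, and the arrays in the fit with the clone as a random block, with and without the replicate number. Others were every array as a separate sample, the parental culture pooled with the vector clones, the mean of all probes of a gene, and each array number or clone left out in turn. The median of the 3 arrays of each clone, the lists in the comparisons with the parental culture, and the values of single KLIP1 clones beside the vector clones were added after the data had been seen. Also added then were the split test of the farthest of 24 lists and that of probes at an unadjusted p under 0.05. An offset of log2(value + 16), meant for linear values, was not run because the values were deposited on the log2 scale.

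The fits were tested on simulated data for KLIP1 against vector with 30968 probes, of which 200 were changed, 50 at each size. Changed probes were drawn from those at or above the median of the vector means, the brightest left out. The recovered shares therefore do not cover dim or near-saturated probes. Clone differences were drawn independently for each probe, so shifts of many probes together were not simulated. Over 10 simulations the fit on clone means recovered 10.4% of changes of 0.5 on the log2 scale, 76.6% of changes of 1, 97.8% of changes of 2 and 99.8% of changes of 4, with 4.88% of its calls false. Over 3 simulations the fit on arrays with the clone as a random block recovered 59.3%, 96.7%, 100% and 100%, with 49.1% of its calls false. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.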

Results

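Expression was profiled in MCF7, an estrogen receptor positive human breast cancer cell line, to examine what overexpression of KLIP1 does to its transcripts. KLIP1 is a centromere protein whose current gene symbol is CENPU, and the platform annotation lists it as MLF1IP. The title of the series names the c-Myc transcription factor as the function of interest. Polyadenylated RNA labelled with Cy5 was hybridised to single-colour Phalanx human arrays. The 24 arrays comprised 1 parental culture, 3 clones stably transfected with the empty vector (A, H and I) and 4 clones stably transfected with KLIP1 (F, H, J and K), each measured on 3 arrays. The submitters call the 3 arrays technical replicates, so the clone was the replicate in the comparisons between groups, with n = 3 vector clones and n = 4 KLIP1 clones, and the parental arm held a single culture. Each array gave values for 30968 probes on the log2 scale, with array medians from 7.011 to 7.031. The number of clones limits the precision of every comparison between groups. Among the 15484 brighter probes the median SD between arrays of a clone was 0.18 and the median SD between clones of a group, net of array spread, was 0.13.

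The first question was whether the clones labelled KLIP1 carried more of the KLIP1 transcript. The CENPU probe (PH_hs_0028863) was higher in all 4 KLIP1 clones than in all 3 vector clones, at 14.14 ± 0.19 (SD, n = 4) against 10.03 ± 0.11 (SD, n = 3). The difference of 4.10 (SE 0.13; limma, adjusted p = 4.3e-07) has a 95% interval of 3.81 to 4.40 and corresponds to 17.2-fold more signal. Clone H held the lowest level, 14.5-fold over the vector mean, and clone K the highest, 20.1-fold. The parental culture, at 9.99, lay inside the range of the vector clones, 9.95 to 10.16. The probe ranked above 88.2% of all probes in the vector clones and above 99.2% in the KLIP1 clones. No array read this probe at the saturated value of 16.

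**Figure D1:**
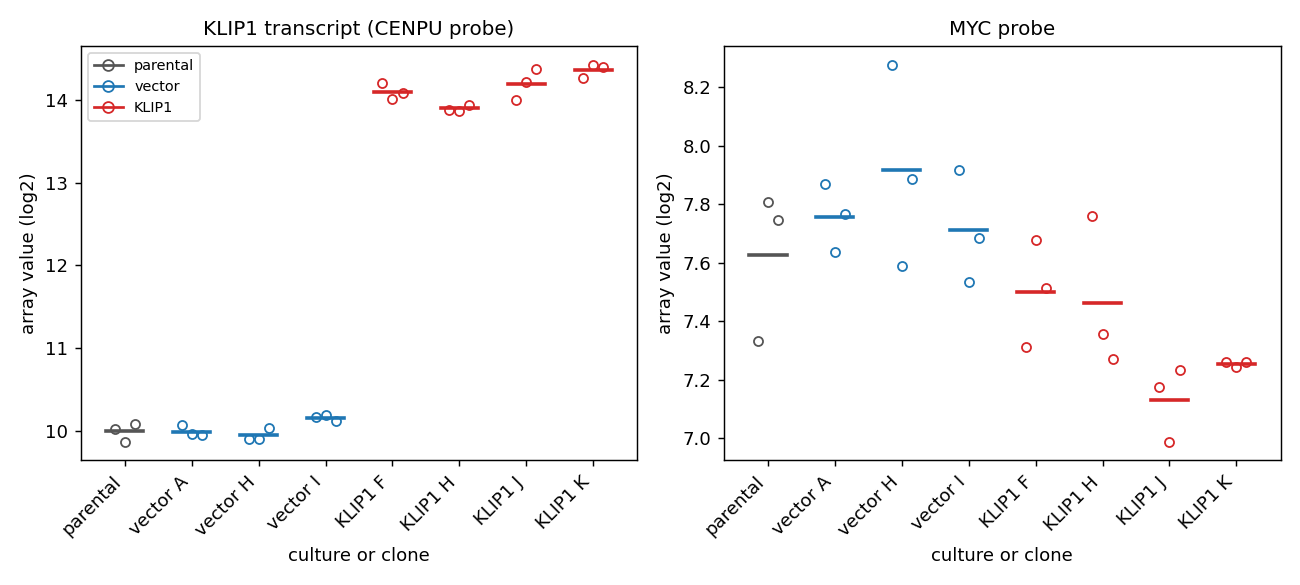
Values of the KLIP1 transcript (CENPU probe, left) and of the MYC probe (right) on the log2 scale, with each open circle an array and each horizontal line the mean of the 3 arrays of a culture or clone. The KLIP1 clones read 13.90 to 14.36 for CENPU against 9.95 to 10.16 in the vector clones, and 7.34 ± 0.17 for MYC (SD of 4 clones) against 7.80 ± 0.11 (SD of 3 clones).

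The comparison of KLIP1 clones with vector clones asked which other transcripts accompany the overexpression. CENPU was the single probe of 30968 past an adjusted p of 0.05 in limma on clone means, while 3301 probes had an unadjusted p under 0.05, 1688 higher and 1613 lower in KLIP1 clones. Independent probes without any difference would give 1548, but other groupings of the same 7 clones gave up to 4063, and without vector clone I the count was 2026. A difference of more than 2-fold was seen for 64 probes, 24 higher and 40 lower. Every KLIP1 clone lay above every vector clone for 2061 probes (6.66%) and below for 1353 (4.37%), where chance gives 5.71% for both directions together. With the arrays in the fit and the clone as a random block, 1234 probes passed in place of 1, 698 higher and 536 lower. On simulated arrays with 200 changed probes that fit made 172 false calls on average, 49.1% of its calls. The fit on clone means made 7.3, or 4.88%. These shares depend on the number of changed probes and on clone differences drawn independently for each probe. They do not give the share of false calls among the 1234.

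MYC itself (PH_hs_0023009) was lower in every KLIP1 clone than in every vector clone, at 7.34 ± 0.17 (SD, n = 4) against 7.80 ± 0.11 (SD, n = 3). The difference of -0.46 (SE 0.13) did not pass the threshold over all probes (limma, adjusted p = 0.403), and neither it nor any other of the 21 measured genes of the MYC network passed when adjusted over the list alone (4 had an unadjusted p under 0.05). With the arrays in the fit MYC passed, at an adjusted p of 0.0286, against 0.233 or higher in every fit on clone values. The parental culture, at 7.63, lay between the groups. The MYC probe read not far above the array medians, at 62.3% in the ranking of probe means, and single arrays of the groups overlapped. Array 1 of KLIP1 clone H read 7.76 and array 2 of vector clone I read 7.54. The MYC dimerisation partner MAX, read by a pair of probes, differed by 0.34 (SE 0.17) and 0.53 (SE 0.16), with adjusted p of 0.512 and 0.403. PIM1, a kinase that cooperates with MYC, differed by 0.36 (SE 0.13), the MAX partner MXD3 by 0.38 (SE 0.16) and the MYC cofactor RUVBL2 by -0.45 (SE 0.20), or by -0.18 (SE 0.14) without vector clone I. Over the network, 10 genes were higher and 11 lower, with a median of -0.01 (camera, adjusted p = 0.922).

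Genes that MYC is known to activate or repress did not pass as groups. Of 63 measured MYC-activated genes, 29 were higher and 34 lower, with a median difference of -0.03 (camera, adjusted p = 0.519; 0.885 with an estimated correlation as the adjusted p). None passed in limma over all probes or when adjusted over the list alone, and 7 had an unadjusted p under 0.05. The members with the smallest p were the nucleolar methyltransferase FBL at -0.81 (SE 0.19), the folate carrier SLC19A1 at 0.56 (SE 0.14), the purine synthesis enzyme GART at -0.60 (SE 0.17) and the ribosome assembly factor RRS1 at -0.54 (SE 0.19), so that they differed in sign. Of 28 MYC-repressed genes, 11 were higher and 17 lower, with a median of -0.07 (adjusted p = 0.922). PDGFRB, a growth factor receptor near the floor of the array at 6.77 against 6.47, passed when adjusted over the list alone with a difference of 0.29 (SE 0.06). The chaperone CLU differed by 1.12 (SE 0.33), the cell cycle inhibitor CDKN2B by -0.77 (SE 0.23) and fibronectin, FN1, by -1.33 (SE 0.42). Vector clone I stood apart for these 3, and without it the differences were 0.70 for CLU, -0.42 for CDKN2B and -0.74 for FN1.

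Genes of the centromere and kinetochore, where KLIP1 acts, did not pass as a group. Of 38 centromere and kinetochore genes, 22 were higher and 16 lower, with a median of 0.07 (camera, adjusted p = 0.423), and none passed in limma when adjusted over the list alone, while 5 had an unadjusted p under 0.05. The kinetochore motor CENPE differed by 0.54 (SE 0.14), the spindle checkpoint protein BUB3 by -0.56 (SE 0.17), the centromere loading factor OIP5 by 0.44 (SE 0.16) and PMF1 by 0.31 (SE 0.13). For OIP5, 1 array of vector clone A read 7.83 against a clone median of 10.11, and with the median of the arrays of each clone the difference was 0.15. Of 41 S phase genes 18 were higher and 23 lower (median -0.04, adjusted p = 0.585), with thymidylate synthase, TYMS, at -0.62 (SE 0.19) and the replicative helicase subunit MCM3 at 0.40 (SE 0.13). Of 39 G2 and M phase genes 18 were higher and 21 lower (median -0.02, adjusted p = 0.498), with ANP32E at -0.56 (SE 0.14). Of 10 replication-dependent histones 5 were higher and 5 lower (median 0.03, adjusted p = 0.922).

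The genes with the smallest p after CENPU, among probes without overlap between the groups whose higher group read at or above the median of all probe means, are given as values, since none passed the threshold (adjusted p 0.149 to 0.403). Higher in every KLIP1 clone than in every vector clone were the sulfate transporter SLC26A2, at 10.48 ± 0.58 against 8.68 ± 0.60 (SD; difference 1.81, SE 0.33), and MSMB, a secreted protein, at 8.81 ± 0.14 against 7.66 ± 0.61. GALNT12, which starts mucin-type O-glycosylation, differed by 0.67 (SE 0.13) and the actin regulator WIPF1 by 0.45 (SE 0.09). A second SLC26A2 probe differed by 1.08 (SE 0.25). The parental culture read 10.52 for SLC26A2, 8.61 for MSMB, 7.68 for GALNT12 and 7.03 for WIPF1, nearer to the KLIP1 than to the vector mean for all 4. Lower in every KLIP1 clone were the zinc finger transcription factor ZNF217, at 12.10 ± 0.12 against 12.89 ± 0.03 (difference -0.79, SE 0.11, adjusted p = 0.204), the mitotic kinesin KIF15 by -0.77 (SE 0.12), the stress-activated kinase MAPKAPK2 by -0.75 (SE 0.12) and the G protein subunit GNB5 by -0.74 (SE 0.12). The complex I subunit NDUFA5 had the smallest adjusted p after CENPU, 0.149, with a difference of -0.63 (SE 0.08) on a dim probe, while its other probe differed by 0.02 (SE 0.06). The KIF15 probe was dimmer still, at 39.1% in the ranking of probe means, and the WIPF1 probe stood at 48.1%. For KIF15 all KLIP1 clones, at 6.37 or lower, and vector clones H and I, at 6.91 and 6.90, read below the array medians. The parental values of ZNF217, KIF15 and MAPKAPK2 (12.50, 6.84 and 12.14) lay between the groups, and that of GNB5, 8.22, lay within the vector range.

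Heat shock genes had the median farthest from 0 among the 24 lists. By the mean they did not stand apart, at -0.147 for heat shock genes and -0.147 for ribosomal proteins. Of 15 measured genes 11 were lower and 4 higher in KLIP1 clones, with a median of -0.25, but the list did not pass (camera, adjusted p = 0.126), and with an estimated correlation the adjusted p was 0.885. When adjusted over the list alone 3 genes passed, all lower, namely the chaperone HSPH1 at -0.53 (SE 0.15), the heat shock transcription factor HSF1 at -0.60 (SE 0.18) and the constitutive chaperone HSPA8 at -0.45 (SE 0.14). Over all probes none did in limma, and 6 had an unadjusted p under 0.05. The co-chaperone BAG3 differed by -0.32 (SE 0.11), and the small heat shock protein HSPB8, which is also estrogen responsive, went the other way at 1.07 (SE 0.40), or 0.58 (SE 0.32) without vector clone I. The other HSPH1 probe differed by -0.35 (SE 0.15) and the other HSPA8 probe by 0.07 (SE 0.10). In the parental culture HSPH1 was at 12.14, HSF1 at 8.86 and HSPA8 at 13.96, each between the group means, which were 12.42 and 11.89 for HSPH1. Against the single parental culture the list's median was 0.09 in vector clones, with 12 genes higher and 3 lower. In KLIP1 clones it was -0.05, with 5 higher and 10 lower.

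Hormone response and lineage genes did not pass as lists. Of 39 estrogen response genes 16 were higher and 23 lower (median -0.11, adjusted p = 0.401), and without vector clone I the median turned to 0.04. The survival factor BCL2 differed by 1.17 (SE 0.33), or by 0.76 without vector clone I, which was the lowest at 7.22, and the growth factor binding protein IGFBP4 by -0.47 (SE 0.12). Of 21 luminal epithelial markers 7 were higher and 14 lower (median -0.05, adjusted p = 0.838), with the tight junction protein CLDN7 at 0.47 (SE 0.13) and the luminal pioneer factor FOXA1 at -0.36 (SE 0.12). Of 30 basal and mesenchymal markers 20 were higher and 10 lower (median 0.03, adjusted p = 0.733). Of 36 interferon response genes 22 were higher and 14 lower (median 0.06, adjusted p = 0.401), with MX1 at 0.34 (SE 0.11). Without KLIP1 clone K this list passed, higher in KLIP1 clones, with a median of 0.12 (camera, adjusted p = 0.00356; adjusted p = 0.749 with an estimated correlation). Its median was 0.02 without KLIP1 clone F or J (adjusted p = 0.739 and 0.625), and also 0.02 without vector clone I. Of 7 measured antigen presentation genes 3 were higher and 4 lower (adjusted p = 0.940).

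Stress, survival and metabolic lists gave the following counts, none past the threshold in camera. Of 32 p53 targets 12 were higher and 20 lower (median -0.09, adjusted p = 0.401), with TRIAP1 at -0.45 (SE 0.11). Of 29 apoptosis regulators 16 were higher and 13 lower (median 0.01, adjusted p = 0.766). Of 31 genes of the unfolded protein and amino acid responses 17 were higher and 14 lower (median 0.05, while camera pointed lower, adjusted p = 0.940), with ATF3 at 0.38 (SE 0.13). Of 29 immediate early genes 14 were higher and 15 lower (median -0.03, adjusted p = 0.874), with KLF10 at -0.64 (SE 0.17) and JUNB at -0.70 (SE 0.20). Of 41 oxidative phosphorylation genes 22 were higher and 19 lower (median 0.01, while camera pointed lower, adjusted p = 0.838). COX4I1, a cytochrome oxidase subunit near the top of the scale, passed when adjusted over that list alone at -0.34 (SE 0.08). Of 32 glycolysis and hypoxia genes 14 were higher and 18 lower (median -0.03, adjusted p = 0.929), and of 22 cholesterol synthesis genes 11 were higher and 11 lower (median 0.02, adjusted p = 0.733). Of 19 ribosomal protein genes 4 were higher and 15 lower (median -0.10, adjusted p = 0.401). RPL13 among them, at -1.11 (SE 0.49), had 1 array of KLIP1 clone F at 6.77 against a clone median of 13.46, and differed by -0.54 with the median of the arrays of each clone. Of 10 housekeeping genes 2 were higher and 8 lower (median -0.14), which did not pass in camera (adjusted p = 0.401) and lay at the threshold in fry (adjusted p = 0.0499).

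Markers of cell types other than the MCF7 line did not pass as groups. Of 16 fibroblast markers 6 were higher and 10 lower (median -0.02, while camera pointed higher, adjusted p = 0.940), PDGFRB being the single member past the threshold when adjusted over the list alone. Of 16 leukocyte and endothelial markers 8 were higher and 8 lower (adjusted p = 0.940). Across all 24 lists none passed in camera with the preset or with an estimated correlation, while 2 and 1 of them had an unadjusted p under 0.05. The median changed sign under at least 1 alternative for 15 of the 24, estrogen response and 14 others with medians from -0.04 to 0.05. Without vector clone I it moved to 0.03 for centromere and kinetochore genes, -0.04 for MYC-repressed genes and -0.04 for p53 targets, and without KLIP1 clone K to -0.02 for ribosomal proteins. Fry's mixed test asks whether genes of a list differ in either direction, without comparing them with other genes. In it 3 lists passed, heat shock (adjusted p = 0.0194), luminal markers (0.0367) and MYC-repressed genes (0.0440). Oxidative phosphorylation (0.0568), estrogen response and S phase genes (both 0.0612) and the MYC network (0.0653) came next. The test therefore does not set the 3 lists apart from the array as a whole.

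**Figure D2:**
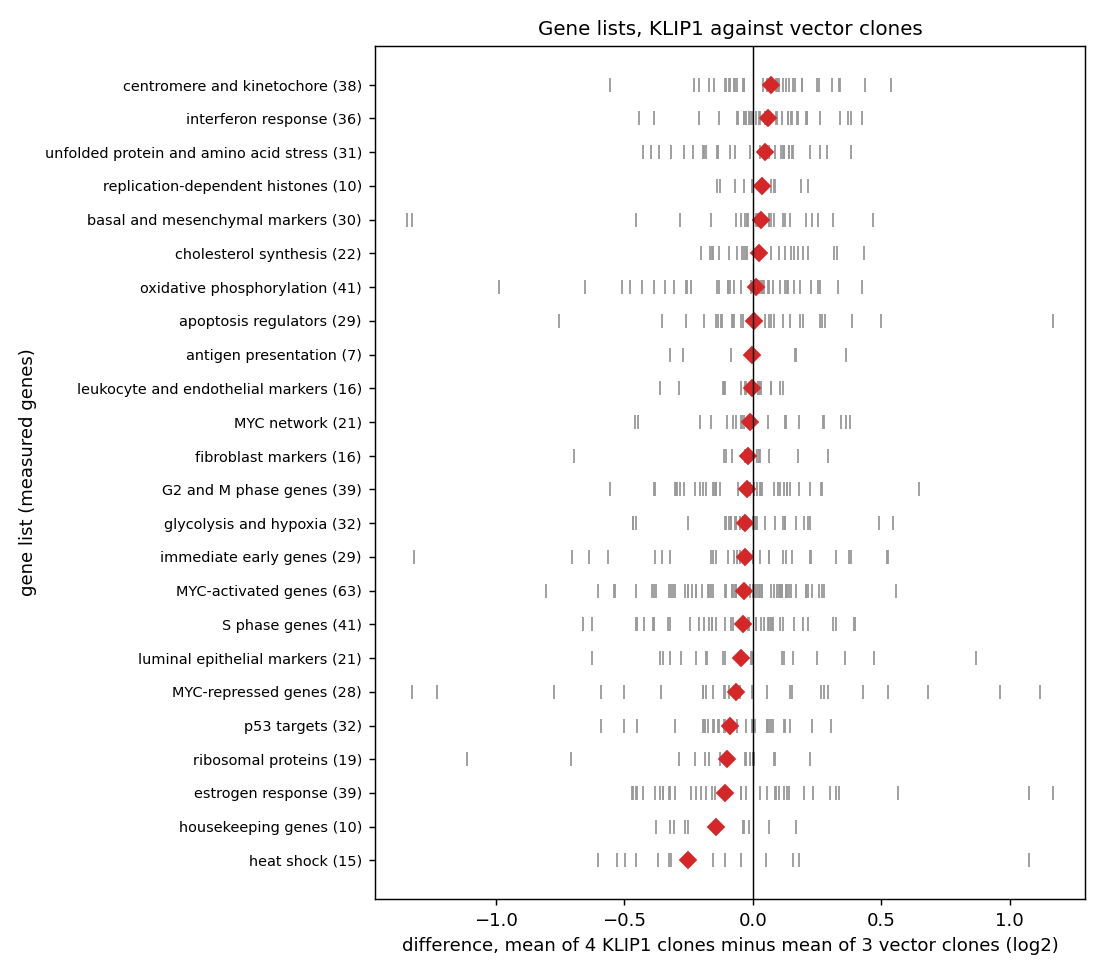
Differences between the mean of the 4 KLIP1 clones and the mean of the 3 vector clones on the log2 scale for the genes of each list, with a grey tick per measured gene, a red diamond at the list's median and the number of measured genes in parentheses. The medians ran from -0.25 for heat shock genes to 0.07 for centromere and kinetochore genes.

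The comparison of vector clones with the parental culture addressed the effect of transfection and cloning alone. A pair of probes passed the threshold (limma on clone means), both without a gene symbol in the annotation used here. PH_hs_0005841 was lower in the vector clones, with a difference of -2.45 (SE 0.18, adjusted p = 0.00151), and PH_hs_0030566 was higher (adjusted p = 0.0441). The latter was saturated on 7 of 9 vector, 11 of 12 KLIP1 and 2 of 3 parental arrays, so its difference cannot be sized. Both calls rested on array 3 of the parental culture, which read 14.45 for PH_hs_0005841 against a parental median of 7.63 and 10.56 for PH_hs_0030566 against a median at the saturated value of 16. Without the arrays numbered 3, or with the median of the 3 arrays of each clone in place of their mean, 0 probes passed in limma (881 and 859 at an unadjusted p under 0.05). With the arrays in the fit and the clone as a random block 34 probes passed, neither of this pair among them. An unadjusted p under 0.05 was given by 624 probes, fewer than the 1548 expected by chance.

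Among named genes none passed in this comparison (adjusted p 0.116 or higher). The mitotic kinase PLK1 was 1.09 higher (SE 0.21) in the vector clones than in the parental culture, the chromatin binding protein BANF1 0.91 higher (SE 0.18), the phosphoprotein adaptor YWHAE 0.95 higher (SE 0.19) and MOB4 1.08 higher (SE 0.20). The RNA helicase MTREX was 1.28 higher (SE 0.23), with parental array 3 at 7.24 against a parental median of 10.50. The transcriptional coregulator TCF20, at -1.41 (SE 0.19), rested on the same array, which read 15.14 against 11.21. The uridine phosphorylase UPP1 differed by -0.68 (SE 0.12), the hypoxia-induced carbonic anhydrase CA9 by -1.23 (SE 0.31), the complex I subunit NDUFS6 by -0.59 (SE 0.14) and NXPH3 by -0.56 (SE 0.14). None of the 24 lists passed in camera, and 3 had an unadjusted p under 0.05.

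KLIP1 clones against the parental culture gave 3 probes past the threshold, CENPU and the same pair of unnamed probes, which share the parental arrays with the comparison above. CENPU was 4.14 higher (SE 0.19, limma, adjusted p = 1.9e-05). PH_hs_0005841 differed by -2.38 (SE 0.17) and the saturated PH_hs_0030566 was again higher (adjusted p = 0.0107), and without the arrays numbered 3 CENPU alone remained. An unadjusted p under 0.05 was given by 1608 probes. PLK1 was 1.36 higher in KLIP1 clones than in the parental culture (SE 0.21, adjusted p = 0.167), BANF1 1.09 higher (SE 0.17) and the actin-associated protein CORO7 0.99 higher (SE 0.16). S100A10, 1.26 higher (SE 0.19), had parental array 3 at 10.55 against a parental median of 14.10. The RNA helicase DHX9 was at 10.41 ± 0.18 in KLIP1 clones (SD, n = 4), 11.17 ± 0.09 in vector clones (SD, n = 3) and 11.90 in the parental culture. Its difference of -1.49 between KLIP1 clones and the parental culture (SE 0.19) had an adjusted p of 0.0874 in limma. TCF20 differed by -1.17 (SE 0.18), UPP1 by -0.65 (SE 0.11), FBXO8 by -1.06 (SE 0.23) and FIBCD1 by -0.90 (SE 0.20). None of the 24 lists passed in camera, and 1 had an unadjusted p under 0.05. The parental arm is 1 culture, assumed in these fits to vary as the clones do.

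Clones within a group differed from each other beyond the spread of their technical replicates. Between the 3 vector clones 2698 probes passed a limma F test, and between the 4 KLIP1 clones 3071 passed. The overlap was 1000 probes, against 268 for independent sets, with the spread estimate shared by both tests. In vector clone I the epithelial keratins KRT13 and KRT15 read 12.14 and 11.53, against 8.22 and 7.87 in clone A, and caveolin, CAV1, read 10.30 against 6.43. The gap junction protein GJA1 (10.33 against 6.81), the imprinted transcript H19 (11.05 against 7.53), the estrogen-induced protease CTSD (13.38 against 10.62) and the matricellular protein CCN5 (14.37 against 11.11) were also higher in clone I than in clone A. The protocadherin PCDH17 (7.35 against 11.30), DSCR8 (7.55 against 11.59) and the dehydrogenase DHRS2 (10.34 against 13.28) were lower. Among KLIP1 clones PCDH17 ran from 10.45 in clone H to 6.55 in clone K, the growth factor BMP7 from 11.92 in clone F to 9.63 in clone K, and the glutamate receptor subunit GRIA2 from 9.17 in clone F to 6.71 in clone J. TIMP3, a protease inhibitor, was highest in clone K, by 2.51 over clone F, and read 6.74 or less in the other KLIP1 clones. All of these passed the F test in the group named. These tests compare the cultures that were arrayed and not the transfected gene. With the arrays of any 1 number left out of every clone, leaving a pair of arrays each, 938 to 1564 probes passed among vector clones and 675 to 1401 among KLIP1 clones.

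Some lists held a larger share of probes past this F test than other named genes did. Each clone is 1 culture set against technical spread, so the p-values describe these cultures alone. Fisher's exact test also takes genes as independent. The estimated correlation was 0.129 for estrogen response and 0.149 for interferon response genes, so at least their p-values are too small. It was -0.014 for MYC-repressed genes and -0.020 for apoptosis regulators. Of 39 estrogen response genes 21 passed among vector clones, against 12.8% of all named genes, and 17 among KLIP1 clones, against 14.3% (Fisher's exact test over 48 tests, adjusted p = 4.8e-08 and 2.2e-04). Examples in vector clones A and I were the trefoil factor TFF3 (11.53 and 13.39), the growth regulator STC2 (8.90 and 10.80) and the zinc transporter SLC39A6 (14.30 and 12.80). Of the MYC-repressed genes 11 of 28 passed among vector clones (adjusted p = 0.00375), CTSD, FN1 and TXNIP among them. Among KLIP1 clones 14 of 36 interferon response genes (adjusted p = 0.00297) and 13 of 29 apoptosis regulators (adjusted p = 0.00117) passed. These calls held when limited to the brighter probes. Immediate early genes (9 of 29 among vector and 10 of 29 among KLIP1 clones, adjusted p = 0.0494 and 0.0361) and luminal markers among vector clones (8 of 21, adjusted p = 0.0247) lost theirs there, with adjusted p of 0.0673, 0.0600 and 0.191.

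**Figure D3:**
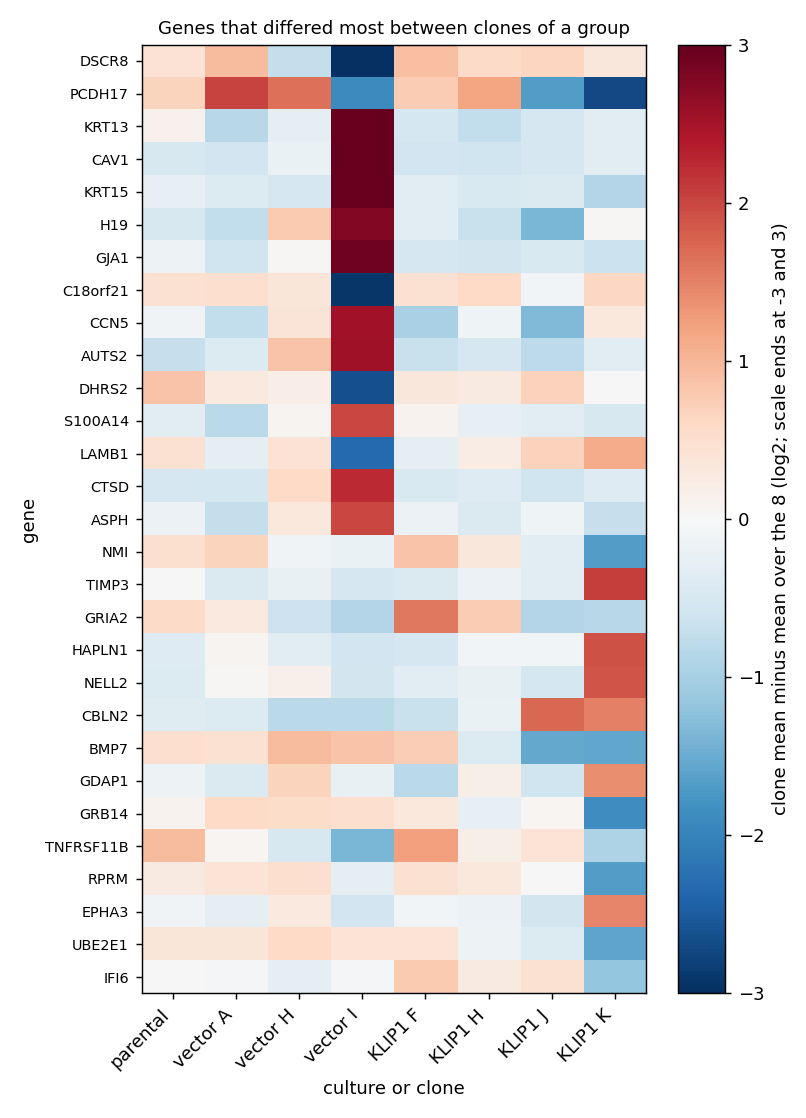
Clone means relative to the mean over the 8 cultures on the log2 scale (colour, ends at -3 and 3) for the 29 genes with the widest range between clones among those past the F test, in the vector group or the KLIP1 group. Vector clone I stands apart for KRT13, CAV1, KRT15 and GJA1, and KLIP1 clone K for TIMP3, HAPLN1 and NELL2.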

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

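The count of splits for probes at an unadjusted p under 0.05 was the test here chosen only after its result was seen. Among the 4 KLIP1 clones, 125 genes and list means were searched for a clone whose gap to the nearest other clone took most of the range over the clones. Chance marks about 1 in 20 groups, 6.25 of 125, and 5 were marked. RPL13, a ribosomal protein, was lower in clone F at 11.36 against 13.67 to 13.72, a gap of 0.982 of the range, and 1 array of that clone read 6.77 against a clone median of 13.46. CA9, a carbonic anhydrase, was lower in clone K at 7.06 against 7.67 to 7.71, a gap of 0.933 of the range. PDGFRA, a growth factor receptor, was higher in clone K at 7.07 against 6.52 to 6.57, a gap of 0.905 of the range. STAT2, a transducer of interferon signals, was higher in clone F at 8.19 against 8.05 to 8.07, a gap of 0.843 of the range. That range was only 0.15, and STAT2 did not pass the F test between KLIP1 clones (adjusted p = 0.795). The mean of the leukocyte and endothelial markers was higher in clone K at 7.20 against 7.06 to 7.09, a gap of 0.831 of the range.

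The number of probes separating KLIP1 from vector clones depended on how clones entered the fit. On clone means 1 probe passed, and 5 of the 35 splits of the 7 clones gave as many, the highest of the others being 1, so chance cannot be excluded for a count of 1, while CENPU itself had an adjusted p of 4.3e-07. Chance cannot be excluded for the 3301 probes at an unadjusted p under 0.05 either, as 4 of 35 splits reached that number and the highest other gave 4063. With arrays in the fit and the clone as a random block 1234 probes passed, and again chance cannot be excluded, as 2 of 35 splits reached that number and the highest other gave 1795, 1.45 times as many. That split set KLIP1 clones H, J and K against the vector clones with KLIP1 clone F. Differences between clones beyond the shared correlation may therefore account for part of the 1234. An effect of KLIP1 in clones H, J and K that is weaker in clone F stays open. Such an effect would not follow the CENPU transcript, which was 16.8-fold over the vector mean in clone F and 14.5-fold in clone H.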

How the results depend on the processing

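The median of the arrays of each clone was the test here chosen only after results were seen. CENPU kept its direction and stayed past the threshold in all 21 alternatives, at 4.03 to 4.19. Counts moved most with every array a separate sample, to 2642 for KLIP1 against vector, 102 for vector against parental and 289 for KLIP1 against parental. With the clone as a random block and without the replicate block 1234 probes passed for KLIP1 against vector, 34 for vector against parental and 94 for KLIP1 against parental, and 1 list, heat shock (adjusted p = 0.0462). On clone means that list had an adjusted p of 0.885 with an estimated correlation. These fits count arrays of a clone as partly or fully independent. With the random block 49.1% of calls were false in simulations with 200 changed probes. The median of the arrays of each clone gave 0 for vector against parental and 1 for KLIP1 against parental, in place of 2 and 3, as it discounts single spots. eBayes without a trend gave 1 for vector against parental and the robust fit 5 for KLIP1 against parental, DHX9 among them, and fry called 1 list, housekeeping genes, with its directional test and 3 others with its mixed test (heat shock 0.0194, luminal markers 0.0367, MYC-repressed genes 0.0440, as adjusted p). For these the cause was not tested.

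With the replicate block added to the random clone the counts were 1019, 28 and 69, no list passed in camera (2 at an unadjusted p under 0.05), and there were 2536 for clone differences among vector clones and 2810 among KLIP1 clones. The numbers do not pair the arrays. Deviations from clone means correlated at -0.015 on average for arrays of the same number (-0.48 to 0.49 over 84 pairs) and at 0.008 for different numbers.

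With 1 clone or 1 array number left out, 1 to 2 probes passed for KLIP1 against vector, the second, SGCE, without vector clone A. For vector against parental 0 to 5 passed and for KLIP1 against parental 1 to 8, the lowest without array number 3 and the highest without number 2. Lists ranged from 0 to 1, interferon response without KLIP1 clone K (adjusted p = 0.00356; adjusted p = 0.749 with an estimated correlation). Clone differences ranged from 938 to 1564 for vector and 675 to 1401 for KLIP1 clones, with fewer arrays per clone by construction. Of 2073 values of 100 named genes under the alternatives, 1899 kept direction and side of the threshold. The other 174 newly passed it, all with the arrays in the fit. On clone values the lowest adjusted p of these genes in limma was 0.0608, for NDUFA5. Of 576 list medians 529 kept direction and side of the threshold and 3 newly passed it. The other 44 differed in sign while not past it, a count that includes medians within rounding of 0. Probes near the floor of 5.81 or at 16 cannot show lower or higher levels. The offset of log2(value + 16) was not run, as the values were deposited on the log2 scale.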

Other observations

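The values of single KLIP1 clones and the test of the farthest of 24 lists over splits of clones were chosen only after results were seen; the other tests on heat shock genes and on splits of arrays were chosen before theirs. Single clones are given without a test, since a clone is 1 sample and its arrays measure technical spread. Of 36 interferon response genes, 26 were above the mean of the 3 vector clones in KLIP1 clone F (median difference 0.13), 25 in clone H (median 0.18), 26 in clone J (median 0.09) and 11 in clone K (median -0.12). The interferon-induced gene IFI6 read 9.52 in clone F and 7.56 in clone K, with 8.47 to 8.68 in vector clones. The transcription factor IRF9 read 9.38 and 8.02 (vector 8.41 to 8.90) and the antiviral gene IFIT1 7.76 and 6.68 (vector 6.91 to 7.33). The membrane protein IFITM1 read 10.15 and 8.47, but vector clones alone ran from 8.92 to 10.11. Other members were higher in clone K than in clone F, such as the antiviral GTPase MX1 at 7.34 against 7.04 (vector 6.78 to 6.85) and EPSTI1 at 7.41 against 7.19 (vector 6.63 to 7.71). NMI, an interferon-inducible partner of STAT proteins, read 9.17 in clone F and 6.64 in clone K (vector 8.13 to 8.99). CENPU was 16.8-fold over vector in clone F and 20.1-fold in clone K.

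Heat shock genes were lower in KLIP1 than in vector clones by a median of -0.25. Against the single parental culture the medians were 0.09 in vector clones and -0.05 in KLIP1 clones. The difference between KLIP1 and vector clones did not pass in camera (adjusted p = 0.126, and 0.885 with an estimated correlation). Nor did it pass in fry's directional test (adjusted p = 0.133), and the list was singled out as the farthest from 0 of 24. Random lists of equally bright genes had medians from -0.12 to 0.15 in their central 95%, centred at 0.007. Genes of that brightness were thus not lower in general. The observed median lay at percentile 0.06 of 10000 such lists. That place is no evidence on chance, since the list was picked for its distance from 0 in the same data. Without any 1 clone the median stayed at -0.17 or lower, so no single clone decided it. Over 35 splits of the clones its distance of 0.25 was the 1 largest, the highest other being 0.20. This decides nothing for a list picked as the farthest. With the farthest of all 24 lists taken anew in each split, the values were again 0.25 and 0.20. That measure was chosen after the list was seen, and 1 of 35 is the smallest share that these splits allow, so it does not exclude chance. Camera and fry's directional test did not call the list. Fry's mixed test did (adjusted p = 0.0194), but it does not compare the list with other genes. A response of chaperone genes to KLIP1 is a hypothesis these data leave open, and a difference in culture between the transfections may equally underlie it and was not tested, since no source used here gives batches.

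Grouping the arrays by clone called more probes than shuffling them between clones of the same group. Among vector clones 2698 probes passed against at most 1529 in the other splits, the real grouping being the 1 highest of 100, and among KLIP1 clones 3071 against at most 1434, again the 1 highest of 100. This decides nothing about chance, since the arrays of a clone are technical replicates and shuffling them sets 1 sample per clone against technical noise; the step at which they were split is not given. Clonal selection, the site of integration and conditions of single cultures therefore cannot be told apart here, nor from technical differences between the samples of each clone.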
